A study of Mus musculus with 40 samples.

How the data were processed

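The study measured transcripts in whole kidney, lung and heart of male C57BL/6 mice on 40 Affymetrix mouse whole-genome arrays, in 8 groups of 5. Per the labels, RNA was extracted with Trizol and hybridised as biotin-labelled cRNA. The processing notes name RMA and Partek 6.6 without saying which step each served. The deposited values are intensity values, linear signals from 0 to 69706.7, scaled so that the mean of each array after trimming 2% at each end is 500. They are not the log2 values that RMA writes, and the summary method behind them is not stated. There are no detection calls. Of the values, 1 was 0 and 3281 were under 1.

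Of 45101 probe sets, 34958 carry 1 gene symbol, 932 several and 9211 none, and 64 are controls; those with 1 symbol cover 18194 genes. Each gene was represented by its probe set with the highest mean. Signals were taken as log2(signal + 16), which understates the fold of dim genes. A gene was tested in a tissue when its highest group mean reached the 40th percentile of all values, a signal of 117.9. Depth on arrays is signal over background: genes under that level were not tested. H19, Ccnb1 and Ddx3y were not among the genes tested. Probe sets with several symbols or none were not used, so a gene can be missing here although the array holds a probe set for it.

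Ages were compared within a tissue with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group means, all ages of the tissue in 1 fit), with the Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The numbers of arrays, 5 per group or 4 where an array was left out, set the precision. Differences between tissues were contrasts of changes in 1 fit of all arrays. Each change is later age over earlier age, and a difference is the first tissue's change minus the second's. Overlaps between tissues were set beside the number expected of independent calls. Tables were read with the data.table package (version 1.17.8) and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

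The 41 gene lists hold 1011 entries, of which 926 matched a gene on the array. Their names are cell cycle, imprinted genes, fetal growth regulators, cell cycle inhibitors and pocket proteins, growth hormone and IGF axis, collagens and extracellular matrix, histone and DNA methylation enzymes, fatty acid oxidation, oxidative phosphorylation, glycolysis, ribosomal proteins, nephron progenitors, proximal tubule, distal nephron, podocyte, male-biased kidney genes, xenobiotic metabolism, alveolar type 2 and type 1 cells, airway cells, alveolar septation, fetal cardiac sarcomere, adult cardiac contraction, endothelium, macrophages, T and NK cells, B and plasma cells, MHC class II and antigen presentation, interferon response, erythroid cells, neutrophils and mast cells, adipocytes, skeletal muscle, thymocytes, liver, adrenal gland, cardiomyocytes in other organs, Schwann cells, circadian clock, immediate early genes and glucocorticoid response. Lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Some genes are in several lists, and many are expressed by the tissue studied.

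The lists, the tests, the threshold and the rule for naming genes were fixed before the data were examined. The rule selects the 10 genes with the largest rises and the 10 with the largest falls among those with an adjusted p under 0.05 and no overlap between the arrays of both ages, for kidney and lung 8 against 1 week and heart 4 against 1 week, leaving out placeholder symbols. For 8 against 4 weeks it selects 5 per direction, for genes shared by the organs 10 per direction, and for each difference between organs 5 per direction. For each list it selects up to 4 members with the largest change among those called, and for every comparison a fixed set of growth and marker genes. The text names part of the genes selected.

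Each array was set against the tissue profiles and the pairing of replicate numbers was checked. Replicate numbers did not pair the arrays: correlations of residuals between arrays with the same number ranged from -0.22 to 0.45, and those with the same animal number had a median of -0.00 (18 pairs) against -0.00 for different numbers (138 pairs). The highest, 0.45, was that of heart replicate 1 at 1 and 4 weeks. Both of these arrays are high in poly-A controls (12.40 and 12.58) and are the heart arrays marked with an upper-case letter in their description. They thus share technical traits. The arrays were nevertheless taken as independent. The fit was tested on simulated data with 200 changed genes, spread over 1.5-fold, 2-fold and 4-fold. At 2-fold the share recovered was 78.8% in heart, 81.3% to 84.9% in kidney and 92.8% to 93.4% in lung. At 1.5-fold it was 41.0% in heart, 48.5% to 48.7% in kidney and 72.8% to 73.1% in lung. Over all folds together 5.1% to 6.7% of calls were false. The simulated spread came from the arrays other than the 2 whose transcripts contradict their label, with 5 arrays in every group. In lung and heart the shares therefore do not describe the fit as labelled, whose spread holds those 2 arrays. Nor do they describe the fit without them, which has 4 arrays at 1 week.

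Alternatives fixed beforehand were no filter or the 60th percentile, the mean of a gene's probe sets, added quantile normalization, median centring, array weights, all arrays in 1 fit, an intensity trend, treat over 1.5-fold, the replicate number as a block, the animal number as a random block, leaving out each array in turn, and both heart arrays marked with an upper-case letter in their description left out. Alternatives chosen after the data were seen were leaving out the 2 arrays that contradict their label, the poly-A control block, leaving out the 4 arrays high in poly-A controls, offsets of 1 and 64, leaving out the lung arrays rich in muscle transcripts, and a separate spread for each tissue. The 4 arrays high in poly-A controls include both marked heart arrays, so in heart these are not separate checks.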

Results

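Transcript levels were measured on 40 arrays, 1 per sample, from kidney, lung and heart of male C57BL/6 mice. Kidney and lung were taken at 1, 4 and 8 weeks of age and heart at 1 and 4 weeks, with 5 arrays in each of the 8 groups. The labels call the organs rapidly proliferating at 1 week, slowly proliferating at 4 weeks and very slowly proliferating at 8 weeks, so each comparison of ages asks which transcripts change as juvenile growth slows. The number of arrays limits the precision of every value below. Errors are standard errors (SE) of log2 changes or standard deviations (SD) of signals. Where the mean signal at either age lies under the 117.9 needed for a test, the fold and its rank depend on the offset of 16 added before taking logs.

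The transcripts on 38 arrays were most like those of the organ on the label, and those on 2 arrays were not. On the array labelled heart 1 week replicate 5 the signal of Sftpc, the surfactant protein C gene of alveolar type 2 cells, was 27190, against 125 to 1072 on the other heart arrays of that age. On the same array Myh6, which encodes the adult cardiac myosin heavy chain, gave 2396 against 36520 to 44800. On the array labelled lung 1 week replicate 4, Sftpc gave 1982 against 23330 to 28920 on the other lung arrays of that age, and Myh6 gave 36020 against 611 to 1868. The labels were kept, the counts of changed genes for lung and heart are given here as labelled and without these 2 arrays (the reduced set), and the gene values and list counts for lung and heart come from the fit without them unless stated. The value as labelled stands beside a gene where its call or direction changed or its fold moved by over 1.5 times. The count as labelled stands beside a list whose call changed or whose larger count moved by at least 1.5 times.

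**Figure D1:**
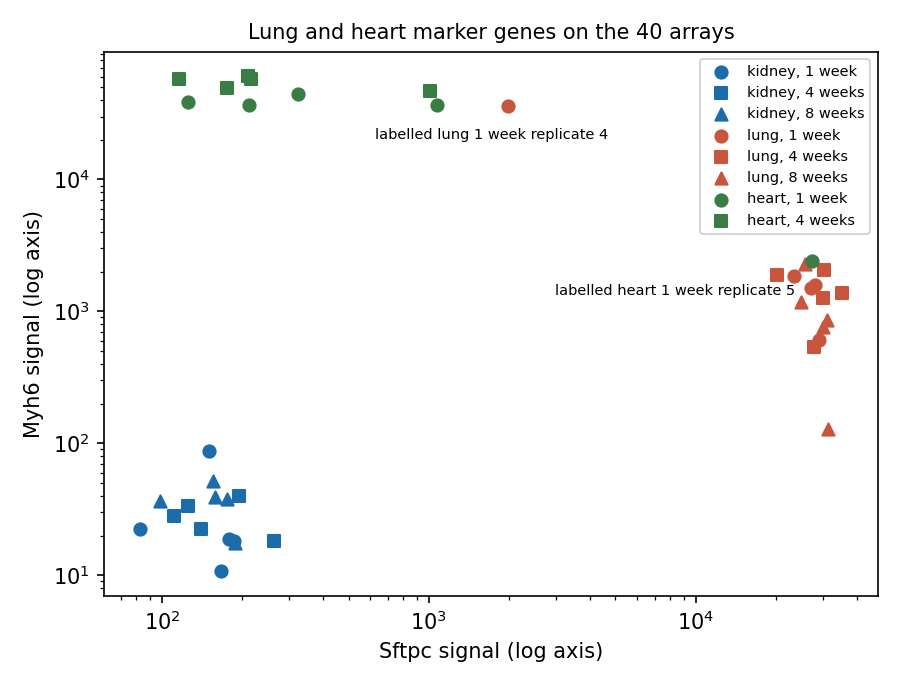
Signal of the lung gene Sftpc (log axis) against signal of the heart gene Myh6 (log axis) on each of the 40 arrays, 1 point per array, coloured by labelled tissue and shaped by age. The array labelled heart 1 week replicate 5 sits among the lung arrays and the array labelled lung 1 week replicate 4 sits beside the heart arrays.

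The kidney at 8 weeks was compared with the kidney at 1 week to ask how the organ of a rapidly growing pup differs from that of a young adult. Genes of tubular transport and of drug metabolism rose, and genes of cell division and extracellular matrix fell. Egf, which encodes the epidermal growth factor precursor made by the distal tubule, rose 23.7-fold (log2 change 4.57, SE 0.14), from a signal of 1067 ± 188 (SD, n = 5) to 25550 ± 3221 (SD, n = 5). Hdc, which encodes the enzyme that makes histamine, fell from 1517 ± 387 (SD, n = 5) to 6.02 ± 1.56 (SD, n = 5), under the offset itself. The size of that fall is set by the offset (log2 change -6.09, SE 0.17, with 16 added). Birc5, which encodes the mitotic protein survivin, fell from 719 ± 124 (SD, n = 5) to 14.9 ± 3.17 (SD, n = 5), and the proliferation marker Mki67 fell from 1325 ± 381 to 114 ± 44.7 (SD, n = 5 each).

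Of 13645 genes tested in kidney, 6472 changed between 1 and 8 weeks at an adjusted p under 0.05 in limma, which is 47.4% of them. Of these, 2660 were higher and 3812 lower at 8 weeks, and 1914 had changed at least 2-fold. The largest rises among genes whose arrays did not overlap between the ages were those of Serpina1f (log2 change 6.29, SE 0.11, adjusted p = 6.5e-15), a serine protease inhibitor gene, and Hpd (5.76), a tyrosine breakdown gene. The steroid dehydrogenase gene Akr1c21 (5.39), the carboxylesterase gene Ces1d (4.99), Dnase1 (4.92), the retinol dehydrogenase gene Rdh16f2 (4.91), the fatty acid desaturase gene Scd1 (4.64), Nat8f5 (4.57), Egf and Guca2b (4.53), which encodes uroguanylin, followed. The largest falls at the offset of 16 were those of Serpina6 (-6.85, SE 0.28), which encodes corticosteroid-binding globulin, Hdc, and Afp (-5.05), which encodes alpha-fetoprotein. Defb19 (-4.63), Birc5 (-4.56), Penk (-4.50), Hmcn1 (-4.33), Atp12a (-4.14), the imprinted cyclin-dependent kinase inhibitor gene Cdkn1c (-4.01) and the basement membrane gene Frem1 (-3.90) came next. The liver gene Alb was at 11530 and 2921 on kidney 1 week replicates 1 and 5 and at 451 to 886 on the other 3, while Serpina6 (8396 to 16320) and Afp (2772 to 5367) were high on all 5. The adrenal list had a mean of 9.11 and 9.13 on replicates 3 and 4 and 6.99 to 7.72 on the others. The actin 3' minus 5' difference, a measure of RNA quality, was 0.34 to 0.51 on the kidneys of 1 week and 0.73 to 0.99 on those of 8 weeks. It moved with age beside these changes.

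Among the gene lists, 51 of 57 measured cell cycle genes fell and none rose (median log2 change -1.84, adjusted p = 7.1e-19), with 51 also falling when adjusted over the list alone. Cenpa, the centromeric histone gene, fell by 3.69 and Melk by 3.44. Of 40 genes of collagens and extracellular matrix, 37 fell and 1 rose (median -2.16, adjusted p = 6.6e-21), the same numbers as adjusted over the list alone; Col1a1 (-3.47), Emilin1 (-3.34) and Postn (-3.14) were among them. Of 22 fetal growth regulators, 19 fell and 2 rose (19 and 2 adjusted over the list alone, adjusted p = 2.5e-08), with Ptn at -3.74, Mest at -3.58 and Gpc3 at -3.37. Of 22 genes of alveolar septation, a list written for lung that holds many matrix and smooth muscle genes, 17 fell and 1 rose, as when adjusted over the list alone (adjusted p = 5.0e-07); Fbn2 fell by 2.69, Acta2 by 2.45 and Tnc by 2.42. In the list of fetal cardiac sarcomere genes, 5 of the 6 measured members fell, all 5 also when adjusted over the list alone (adjusted p = 7.2e-04), with the smooth muscle genes Acta2 and Myl9 (-1.93) the farthest.

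Of 34 proximal tubule transporter genes, 32 rose and none fell (median 1.29, adjusted p = 1.6e-21), and 33 rose when adjusted over the list alone. The organic anion transporter gene Slc22a7 rose by 4.18 and the dicarboxylate transporter gene Slc13a3 by 2.87. Of 36 genes of xenobiotic metabolism, 26 rose and 4 fell (26 and 4 adjusted over the list alone, adjusted p = 1.5e-12), with Ugt3a1 at 3.97, Cyp4b1 at 3.68 and Cyp2e1 at 3.30. Of 23 genes of the distal nephron and collecting duct, 16 rose and 4 fell (16 and 4 adjusted over the list alone, adjusted p = 5.4e-05), among them Pvalb (1.97), the chloride-bicarbonate exchanger gene Slc26a4 (1.27) and Slc12a3 (1.16), the target of thiazide diuretics. Of 13 genes known for higher levels in male kidney, 9 rose and 4 fell (9 and 4 adjusted over the list alone, adjusted p = 0.0054), with Cyp2d12 at 3.76 and Hsd11b1 at 2.29. Of 19 clock genes, 10 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 0.00135), with Dbp at 2.94, Nr1d1 at 2.42 and Npas2 at -1.96.

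Of the 20 lists called in this comparison, the 10 in the preceding paragraphs also passed with a correlation between genes estimated per list, with adjusted p values from 0.00399 for proximal tubule transport to 0.0357 for the male-biased genes. The other 10 did not. Of 50 genes of oxidative phosphorylation, 49 rose, among them Sdhb (0.99), and Cox8b fell by 2.10 (49 and 1 adjusted over the list alone, adjusted p = 1.1e-13; adjusted p = 0.198 with an estimated correlation). Of 29 genes of fatty acid oxidation, 18 rose and 1 fell (18 and 2 adjusted over the list alone, adjusted p = 4.5e-06; adjusted p = 0.141 with an estimated correlation), with Ppara, the fatty acid sensing receptor gene, at 1.88 and Bdh1 at 1.46. Of 17 genes of MHC class II and antigen presentation, 11 rose and none fell (11 adjusted over the list alone, adjusted p = 2.7e-05; adjusted p = 0.141 with an estimated correlation), with H2-Aa at 3.44 and Cd74 at 2.52. Of 22 imprinted genes, 11 fell and 2 rose (12 and 3 adjusted over the list alone, adjusted p = 4.5e-04; adjusted p = 0.061 with an estimated correlation), among them Cdkn1c, Mest, Nnat (-3.37) and Igf2 (-2.30, SE 0.19). Of 28 genes of histone and DNA methylation enzymes, 16 fell and 1 rose (17 and 1 adjusted over the list alone, adjusted p = 1.0e-04; adjusted p = 0.0582 with an estimated correlation), with Uhrf1 at -2.93 and Ezh2 at -1.89.

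Of 11 podocyte and glomerulus genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 7.5e-04; adjusted p = 0.124 with an estimated correlation), with Wt1 at -1.99 and Synpo at -1.51. Of 21 endothelial genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone, adjusted p = 2.4e-04; adjusted p = 0.0796 with an estimated correlation), with Aplnr at -2.71 and Cldn5 at -1.69. Of 18 glycolysis genes, 11 rose and 2 fell (12 and 4 adjusted over the list alone, adjusted p = 0.0226; adjusted p = 0.269 with an estimated correlation), with Aldoc at 0.99 and Slc2a4 at 0.86. Of 18 glucocorticoid response genes, 11 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 0.0245; adjusted p = 0.269 with an estimated correlation), with Errfi1 at 2.92 and Klf15 at 2.41. Of 26 interferon response genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.0246; adjusted p = 0.581 with an estimated correlation), with Cxcl9 at 2.32. Of 19 genes of the growth hormone and IGF axis, 8 rose and 6 fell and the list was not called (adjusted p = 0.301); Ghr, the growth hormone receptor gene, rose by 1.78 while Igf1 fell by 1.13.

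The kidney at 4 weeks was compared with that at 1 week for the first step of this change. At 4 weeks 5827 genes had changed, 2367 higher and 3460 lower, 1655 of them at least 2-fold. The fetal growth regulators Ptn (-3.87), Mest (-3.66) and Gpc3 (-2.78) fell, as did Cdkn1c (-3.70), Nnat (-2.84) and the imprinted signalling gene Dlk1 (-2.61). Egf rose by 4.45 and Ces1d by 5.25. Igf2, which encodes the fetal growth factor, fell 4.84-fold (log2 change -2.27, SE 0.19), and the growth genes Plagl1 (-1.48), E2f3 (-1.09), Mycn (-1.02) and Igf2bp3 (-0.95) fell with it.

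The same 20 lists were called as between 1 and 8 weeks, 11 of them with an estimated correlation. In this step 50 of 57 cell cycle genes fell (51 adjusted over the list alone, adjusted p = 2.4e-13), with Bub1b at -3.02 and Top2a at -1.94, and 37 of 40 matrix genes fell while 1 rose (38 and 2 adjusted over the list alone, adjusted p = 8.7e-21), with Postn at -3.16 and Lama4 at -2.85. Of 34 proximal tubule genes 32 rose, also when adjusted over the list alone (adjusted p = 3.5e-23), with Slc22a7 at 3.31 and Slc34a3, a renal phosphate transporter gene, at 2.62. Of 29 fatty acid oxidation genes 23 rose (24 adjusted over the list alone, adjusted p = 5.5e-10; adjusted p = 0.0548 with an estimated correlation), with Ppara at 1.88 and Pdk4 at 1.54. Of 50 oxidative phosphorylation genes 47 rose (49 adjusted over the list alone, adjusted p = 3.4e-14; adjusted p = 0.173 with an estimated correlation), with Ndufs1 at 0.96. Of 22 imprinted genes 12 fell and 1 rose, as when adjusted over the list alone (adjusted p = 8.7e-05), and this list also passed with an estimated correlation (adjusted p = 0.0402).

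Between 4 and 8 weeks the kidney was compared for change that went on as growth became very slow. Cell cycle and matrix genes fell further: 17 of 57 cell cycle genes fell (35 adjusted over the list alone, adjusted p = 2.3e-39), with Birc5 at -2.82 (SE 0.14), Cenpa at -1.81, Nuf2 at -1.70 and Mki67 at -1.50. Of 40 matrix genes 5 fell (16 adjusted over the list alone, with 1 rising, adjusted p = 1.6e-13), among them Col1a1 (-1.21) and Col6a1 (-0.72). Bhmt, which encodes an enzyme of the methionine cycle, rose 6.28-fold (log2 change 2.65, SE 0.20), followed by Ceacam2 (1.93), the apolipoprotein B gene Apob (1.47), Tssk4 (1.33) and Akr1c14 (1.28). Serpina6 fell by 3.57 (SE 0.28), and Fignl1 (-2.26), which takes part in DNA repair, fell beside the cell cycle genes. In all, 85 genes changed, 31 higher and 54 lower, 29 of them at least 2-fold.

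The cell cycle and matrix lists passed with an estimated correlation (adjusted p = 0.00916 and 0.0202) and the other 5 called lists did not. Of 17 antigen presentation genes 2 rose, H2-Aa (0.89) and Cd74 (0.80) (6 adjusted over the list alone, adjusted p = 2.5e-10; adjusted p = 0.108 with an estimated correlation). Of 36 xenobiotic genes 2 rose, Aldh1a1 (0.78) and Cyp1b1 (0.48) (4 and 1 falling adjusted over the list alone, adjusted p = 5.6e-04; adjusted p = 0.185 with an estimated correlation). Uhrf1 (-0.95) was the methylation enzyme gene that fell (1 adjusted over the list alone, list adjusted p = 0.0258; adjusted p = 0.514 with an estimated correlation). No fatty acid oxidation gene passed over all genes (2 fell adjusted over the list alone, list adjusted p = 0.00886; adjusted p = 0.673 with an estimated correlation), and no macrophage gene passed either way (list adjusted p = 0.0257; adjusted p = 0.514 with an estimated correlation). In limma 1085 of the 13645 genes had an unadjusted p under 0.05. The count was 55 without kidney 4 weeks replicate 4, 50 without kidney 8 weeks replicate 2, and 139 with the arrays that had high labelling controls set as a block, a choice made after the data were seen. Fignl1, at -2.26 here, was at 0.27 (adjusted p = 0.88) with quantile normalization added. The probe set with the highest mean was chosen anew under each normalization and offset. Both values can therefore come from different probe sets of Fignl1, which was not checked, and its fall is uncertain.

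Of the 85 genes, 66 had changed in the same direction between 1 and 4 weeks (21 rose in both steps and 45 fell in both) and 13 in the opposite direction. Leaving out 1 array at a time put the count of 66 at 43 to 83. Both steps share the 4-week arrays, which pushes chance calls toward opposite directions. Independent calls would give 19.1 in the same direction and 17.2 in the opposite one. The 0 from 20 simulations with no change is fixed by the lack of any change and is no test of the 66. With the 4-week arrays split between the steps, the medians were 28.75 same and 2 opposite over 10 splits. Each step then had only part of the 4-week arrays and its own calls. These medians therefore cannot be set against the 66 or the numbers for independent calls. The covariance of both changes across genes was 0.029312, against -0.021008 in the simulations.

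**Figure D2:**
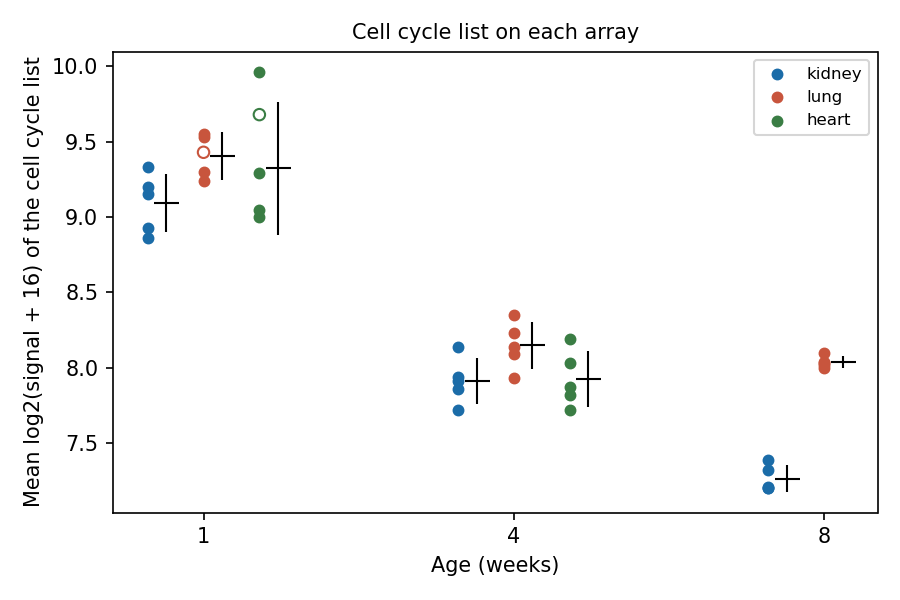
Mean log2(signal + 16) of the cell cycle list on each array by age in weeks, 1 point per array, with bars for the mean ± SD of each group. Open circles are the 2 arrays whose transcripts contradict their label, which the bars leave out; the group mean fell from 7.92 to 7.26 between 4 and 8 weeks in kidney and from 8.15 to 8.04 in lung.

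The lung at 8 weeks was compared with the lung at 1 week for the same question as in kidney. Genes of cell division and septation fell, while genes of antigen presentation and drug metabolism rose. Klf15, a glucocorticoid-responsive transcription factor gene, rose 28.8-fold (log2 change 4.85, SE 0.13), from a signal of 37.8 ± 6.13 (SD, n = 4) to 1544 ± 294 (SD, n = 5). Agt, the angiotensinogen gene, fell 46.8-fold (log2 change -5.55, SE 0.16; 23.6-fold as labelled), to a signal of 17.4 ± 7.96 (SD, n = 5) at 8 weeks. Eln, which encodes elastin, fell from 19380 ± 2579 (SD, n = 4) to 3099 ± 799 (SD, n = 5).

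Of 13736 genes, 4629 changed as labelled (2407 higher, 2222 lower, 1292 at least 2-fold). In the reduced set 6075 of 13706 did (3049 higher, 3026 lower, 1198 at least 2-fold), and 4472 genes, 96.6% of those called as labelled, were called in the same direction in both fits. The largest rises after Klf15 were those of Ms4a4d (4.82), the heat shock genes Hspa1b (4.54) and Hspa1a (4.27), Lrat (4.47), which stores vitamin A as esters, Inmt (4.39; 37.0-fold as labelled against 21.0-fold) and the glucocorticoid-responsive gene Zbtb16 (4.28). Serpina3n (3.87), Cyp2b10 (3.87) and the lipogenic gene Thrsp (3.39) followed. After Agt the largest falls were those of Slc4a1 (-4.64), the anion exchanger gene of red blood cells, Stfa2l1 (-4.62; 15.6-fold as labelled against 24.6-fold), Tnc (-4.47), Prss35 (-4.47; 13.7-fold as labelled against 22.1-fold) and Mest (-4.10). Ucp1 (-3.88; 8.57-fold as labelled against 14.7-fold), the uncoupling protein gene of brown fat, Vcan (-3.86), Stfa3 (-3.75) and Dlk1 (-3.75) came next.

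Of 58 cell cycle genes 56 fell, also when adjusted over the list alone (median -1.35, adjusted p = 5.7e-24), with Ube2c at -2.38 and Gins2 at -2.37. Of 40 matrix genes 32 fell and 5 rose (33 and 5 adjusted over the list alone, adjusted p = 7.3e-12), with Fbn2 at -3.47. Of 21 septation genes 15 fell and 3 rose (16 and 3 adjusted over the list alone, adjusted p = 4.4e-08), with Tnc, Fbn2 and Eln (-2.66); as labelled 10 fell. Of 21 imprinted genes 17 fell and 1 rose, as when adjusted over the list alone (adjusted p = 1.1e-08), with Peg3 at -3.06 and Igf2 at -2.22, and of 21 fetal growth regulators 17 fell and 1 rose (17 and 2 adjusted over the list alone, adjusted p = 1.5e-09), with Mdk at -3.38, Mycn at -2.82 and Gpc3 at -1.22 (as labelled adjusted p = 0.0642). Ghr fell by 0.46 (as labelled adjusted p = 0.13). Of 17 antigen presentation genes 16 rose, also when adjusted over the list alone (adjusted p = 1.6e-11), with H2-Eb1 at 2.26 and Nlrc5 at 1.60. Of 35 xenobiotic genes 25 rose and 1 fell (27 and 1 adjusted over the list alone, adjusted p = 5.3e-12), with Cyp2b10 and Cyp1a1 (3.18), and of 18 glucocorticoid response genes 14 rose and none fell (15 adjusted over the list alone, adjusted p = 4.4e-10), with Klf9 at 2.54.

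These 8 lists were the ones of the 19 called without the 2 arrays that passed with an estimated correlation, at adjusted p values from 0.0157 to 0.0492. Of 19 T and NK cell genes 17 rose and 1 fell, as when adjusted over the list alone (adjusted p = 4.2e-07; adjusted p = 0.152 with an estimated correlation), with Gzma at 2.96 and Klrd1 at 2.08. Of 14 B and plasma cell genes 10 rose, also when adjusted over the list alone (adjusted p = 0.00174; adjusted p = 0.505 with an estimated correlation), with Jchain at 3.25. The list mean was 10.03 on lung 8 weeks replicate 3, which also held the most skeletal muscle transcripts. It was 8.43 to 8.73 on the other lungs of that age. Of 21 macrophage genes 14 rose, also when adjusted over the list alone (adjusted p = 1.8e-05; adjusted p = 0.0987 with an estimated correlation), with Chil3 at 3.24 (21.6-fold as labelled against 9.47-fold) and Pparg at 1.53. Of 27 interferon response genes 23 rose and 1 fell, as when adjusted over the list alone (adjusted p = 1.3e-09; adjusted p = 0.0797 with an estimated correlation), with Ifi27l2a at 2.61. Of 19 airway genes 16 rose, also when adjusted over the list alone (adjusted p = 1.9e-07; adjusted p = 0.0815 with an estimated correlation), with Bpifa1 at 3.12. Of 12 erythroid genes 9 fell (10 adjusted over the list alone, adjusted p = 2.0e-04; adjusted p = 0.236 with an estimated correlation), with Alas2 at -2.73. Of 23 immediate early genes 16 rose, also when adjusted over the list alone (adjusted p = 2.6e-06; adjusted p = 0.0797 with an estimated correlation), with Egr1 at 2.10 and Fos at 2.24.

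Of 19 alveolar type 2 cell genes 14 rose, also when adjusted over the list alone (adjusted p = 1.0e-04; adjusted p = 0.336 with an estimated correlation), with Fasn, the fatty acid synthase gene, at 1.17; as labelled 2 did, also when adjusted over the list alone. Sftpc itself was at 0.09 (adjusted p = 0.641; as labelled 0.84, adjusted p = 0.276). Of 14 alveolar type 1 cell genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.00182; adjusted p = 0.336 with an estimated correlation), with Clic5 at 1.00 and Hopx at 0.81; as labelled 4 rose. Of 28 methylation enzyme genes 13 fell and 4 rose, as when adjusted over the list alone (adjusted p = 0.0201; adjusted p = 0.336 with an estimated correlation), with Uhrf1 at -1.85. Of 19 clock genes 12 rose and 4 fell, as when adjusted over the list alone (adjusted p = 0.00174; adjusted p = 0.061 with an estimated correlation), with Nr1d1 at 3.35. As labelled 23 lists were called. The lists of cell cycle, imprinted, fetal growth, matrix, clock and glucocorticoid genes then passed with an estimated correlation, and those of septation (adjusted p = 0.519), antigen presentation (0.11) and xenobiotic metabolism (0.0983) did not. Oxidative phosphorylation was among the 23 (adjusted p = 0.00215; adjusted p = 0.747 with an estimated correlation) and was not called without the 2 arrays (adjusted p = 0.314).

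The lung at 4 weeks was compared with that at 1 week for the first step. Klf15 (4.65), Zbtb16 (4.55), Bpifa1 (4.16) and Cyp2b10 (4.00) rose, and Tnc (-4.01), Dlk1 (-3.56), Vcan (-3.49), Mest (-3.40) and Fbn2 (-3.06) fell. Igf2 fell by 1.99 (SE 0.15), and Mycn (-2.37) and Igf2bp3 (-1.23) fell too. Cdkn1c was at -0.23 (adjusted p = 0.0359) and as labelled at 0.03 (adjusted p = 0.941), and Gpc3 was at -0.80 and as labelled at -0.40 (adjusted p = 0.377). As labelled 3982 genes changed (2107 higher, 1875 lower, 1106 at least 2-fold). In the reduced set 5484 did (2757 higher, 2727 lower, 956 at least 2-fold), and 3852 genes, 96.7% of those called as labelled, were called in the same direction in both fits.

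The same 19 lists were called as between 1 and 8 weeks (23 as labelled, where the same 6 passed with an estimated correlation). Of 58 cell cycle genes 54 fell (55 adjusted over the list alone, adjusted p = 1.2e-24), with Ube2c at -2.29. Of 35 xenobiotic genes 25 rose (28 adjusted over the list alone, adjusted p = 1.0e-13; as labelled adjusted p = 0.0821 with an estimated correlation), with Cyp1a1 at 2.95. Of 14 alveolar type 1 cell genes 11 rose and 1 fell, as when adjusted over the list alone (adjusted p = 3.1e-04; adjusted p = 0.272 with an estimated correlation), with Clic5 at 1.16; as labelled 5 rose (6 adjusted over the list alone). Of 19 airway genes 16 rose (17 adjusted over the list alone, adjusted p = 5.5e-09; adjusted p = 0.0606 with an estimated correlation). Of 17 antigen presentation genes 16 rose, also when adjusted over the list alone (adjusted p = 8.4e-10; as labelled adjusted p = 0.188 with an estimated correlation), with H2-Eb1 at 1.51.

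Between 4 and 8 weeks the lung was compared for later change. Eln fell by 1.15 (SE 0.15) and Mest by 0.70 in both fits. Arntl, which drives the clock feedback loop, rose by 1.33 (SE 0.15) while its target Per3 fell by 0.92, both also as labelled. Diaph3, a gene of cytokinesis, fell by 1.53 (SE 0.23). Further genes passed without the 2 arrays alone. Among them Vps33b (1.26, as labelled adjusted p = 0.141), Egr1 (1.07, 0.0698), Igha (0.95, 0.123) and Spon2 (0.95, 0.0937) rose. Ccna1 (-1.61, 0.198), Spink5 (-1.43, 0.499), Spata3 (-1.38, 0.147) and Mettl21e (-1.30, 0.532) fell. The cyclin-dependent kinase inhibitor gene Cdkn1c (-0.58, 0.424) and the fetal growth regulator Gpc3 (-0.41, 0.866) fell too. The changes of the genes just named are the same in both fits, and their spread is not.

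As labelled 15 genes changed (4 higher, 11 lower, 3 at least 2-fold), among them Ahnak2 (0.68), Cdkn1a (0.74), Prex1 (0.56), C1qtnf6 (-0.95) and Tspan4 (-0.91). In the reduced set 281 did (125 higher, 156 lower, 14 at least 2-fold), and all 15 (100%) were called in the same direction. Of 40 matrix genes 11 fell (24 adjusted over the list alone, with 1 rising, adjusted p = 7.3e-15; adjusted p = 0.0896 with an estimated correlation); as labelled 2 fell (15 and 1 adjusted over the list alone, adjusted p = 6.4e-15), and there the list passed with an estimated correlation (adjusted p = 0.0138). Of 17 antigen presentation genes 6 rose (9 adjusted over the list alone, adjusted p = 1.3e-08; adjusted p = 0.0896 with an estimated correlation) and as labelled none did (3 adjusted over the list alone), with H2-Eb1 at 0.75 (as labelled adjusted p = 0.493). Of 16 skeletal muscle genes none passed in limma over all genes, 11 rose when adjusted over the list alone, and the list was called (median 2.03, adjusted p = 8.1e-08; adjusted p = 0.375 with an estimated correlation). Of 58 cell cycle genes 1 fell, Prim1 at -0.46 (as labelled adjusted p = 0.123), also when adjusted over the list alone (list median -0.10, adjusted p = 0.0148; adjusted p = 0.867 with an estimated correlation). In all 14 lists were called without the 2 arrays and none with an estimated correlation; as labelled 11 were, 1 with an estimated correlation.

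The count of 15 as labelled was 8 without lung 4 weeks replicate 4. The count of 281 moved with single arrays as well. It was 115, 166, 176 and 151 without lung 4 weeks replicates 2, 3, 4 and 5, and 162, 140, 129 and 184 without lung 8 weeks replicates 1, 2, 3 and 4. Without the 5 lung arrays richest in skeletal muscle transcripts it was 9, and without the 4 over 1 log2 unit above the lung median it was 56; both sets were chosen after the data were seen. Of the 281 genes 131 had changed in the same direction between 1 and 4 weeks and 74 in the opposite one, against 56.2 same and 56.25 opposite for independent calls. The 131 and the 74 thus both exceeded independent calls. With the 4-week arrays split the medians were 36.75 same and 14.25 opposite, which as in kidney cannot be set against the other counts. The changes of both steps had a correlation of 0.02 across genes. The covariance was 0.00306 against -0.013136 in 20 simulations with no change, whose 0 genes are again no test. As labelled the numbers were 9 same and 5 opposite, against 2.12 same and 2.23 opposite for independent calls, with a covariance of 0.0011815 against -0.02955. The splits had medians of 1 same and 2 opposite as labelled.

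The heart at 4 weeks was compared with the heart at 1 week, the only age step measured in that organ. Without the 2 arrays most cell cycle genes fell and most genes of mitochondrial respiration rose. Neither list passed with an estimated correlation (adjusted p = 0.18 and 0.3). Tnni1, which encodes the slow skeletal troponin I of the fetal heart, fell 448-fold (log2 change -8.81, SE 0.16; 183-fold as labelled), from a signal of 19040 ± 2227 (SD, n = 4) to 27.0 ± 9.14 (SD, n = 5). Myh7, the fetal myosin heavy chain gene of the mouse ventricle, fell by 2.68 (as labelled -1.91, adjusted p = 0.125), and Myh6 rose by 0.48 (as labelled 1.28, adjusted p = 0.223). Rpl3l, a ribosomal protein gene of striated muscle, rose by 3.51 (11.4-fold, 19.4-fold as labelled), and Kcnd2, a potassium channel gene, by 2.34.

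As labelled 2451 of 12911 genes changed (901 higher, 1550 lower, 894 at least 2-fold). In the reduced set 3404 of 12792 did (1508 higher, 1896 lower, 847 at least 2-fold), and 2380 genes, 97.1% of those called as labelled, were called in the same direction in both fits. As labelled the count was 1615 without heart 4 weeks replicate 2 and 1609 without heart 4 weeks replicate 5. Other large rises were those of Ces1d (3.67; as labelled 2.62, adjusted p = 0.0738), Zbtb16 (3.47), the purine breakdown gene Xdh (3.40), Lrat (3.22), Gsta3 (3.21; 5.48-fold as labelled against 9.26-fold), H2-Ab1 (3.20; 6.11-fold as labelled against 9.17-fold), Cbr2 (3.12; as labelled adjusted p = 0.368), Ccl6 (3.00; as labelled adjusted p = 0.0885) and the macrophage scavenger receptor gene Cd163 (2.99). Other large falls were those of Bex1 (-3.91), Cpa1 (-3.49), Cited1 (-3.46; 6.12-fold as labelled), Tmem255a (-3.25), Ptn (-3.21), Rrm2 (-3.07), Tnc (-3.05; 12.4-fold as labelled against 8.29-fold), Mt3 (-3.03; as labelled -2.20, adjusted p = 0.0973) and Kcne1 (-2.99; as labelled -1.50, adjusted p = 0.442).

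Of 50 oxidative phosphorylation genes 41 rose (47 adjusted over the list alone, adjusted p = 2.8e-16; adjusted p = 0.3 with an estimated correlation), with Cox7a1 at 1.51 (as labelled 2.63, adjusted p = 0.0811); as labelled none passed in limma over all genes or over the list alone. Of 27 adult contractile genes 20 rose and 1 fell (22 and 1 adjusted over the list alone, adjusted p = 1.5e-08; adjusted p = 0.201 with an estimated correlation), with Kcnd2 and Ckmt2 (1.07; as labelled 2.45, adjusted p = 0.171); as labelled 3 rose. Of 15 fetal sarcomere genes 7 fell and 1 rose, as when adjusted over the list alone (adjusted p = 0.0441; adjusted p = 0.313 with an estimated correlation), with Cnn1 at -1.89 beside Tnni1 and Myh7; as labelled 4 fell and the list was not called (adjusted p = 0.676). Of 58 cell cycle genes 49 fell (52 adjusted over the list alone, adjusted p = 1.9e-19; adjusted p = 0.18 with an estimated correlation), with Bub1b at -2.66. Of 40 matrix genes 31 fell and 3 rose, as when adjusted over the list alone (adjusted p = 4.0e-12; adjusted p = 0.135 with an estimated correlation), with Fbn2 at -2.96 and Eln at -2.84. Of 21 fetal growth regulators 15 fell and 1 rose, as when adjusted over the list alone (adjusted p = 2.9e-07; adjusted p = 0.0721 with an estimated correlation), with Mest at -2.82 and Igf2 at -2.58. Of 29 fatty acid oxidation genes 12 rose and 2 fell (12 and 3 adjusted over the list alone, adjusted p = 2.7e-05; adjusted p = 0.201 with an estimated correlation), with Bdh1 at 2.07; as labelled 4 rose.

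Of 28 xenobiotic genes 18 rose (19 adjusted over the list alone, adjusted p = 1.3e-11), with Gstk1 at 2.00; as labelled 8 of 29 rose. Of 19 macrophage genes 12 rose and 2 fell, as when adjusted over the list alone (adjusted p = 6.0e-07), with C1qc at 2.00 and C1qa at 1.89; as labelled 7 rose. These lists passed with an estimated correlation (adjusted p = 0.0195 and 0.042) and the other 22 of the 24 called without the 2 arrays did not; as labelled 18 were called and none with an estimated correlation. Of 17 antigen presentation genes 13 rose (14 adjusted over the list alone, adjusted p = 1.3e-09; adjusted p = 0.144 with an estimated correlation), with H2-K1 at 1.55; as labelled 6 rose. Of 27 interferon response genes 19 rose (22 adjusted over the list alone, adjusted p = 1.0e-12; adjusted p = 0.147 with an estimated correlation), with Cxcl9 at 2.33 and Oas2 at 1.76. Of 12 genes of the cardiomyocyte list 6 rose, also when adjusted over the list alone (adjusted p = 0.0105; adjusted p = 0.304 with an estimated correlation), among them Tnni3 (0.66; as labelled 1.75, adjusted p = 0.215); as labelled none did.

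The changes from 1 to 4 weeks were then set side by side in the 3 organs to ask which are common. Without the 2 arrays 794 genes were lower in all 3 organs, where independent calls would give 100.2, and 323 were higher, against 38.5; as labelled the numbers were 559 against 58.7 and 153 against 17.0. Among those lowest throughout were Mest (kidney -3.66, lung -3.40, heart -2.82), Fbn2 (-2.79, -3.06, -2.96), Igf2 (-2.27, -1.99, -2.58), Tnc (-1.97, -4.01, -3.05), Ube2c (-1.92, -2.29, -2.63) and Mki67 (-1.90, -2.01, -1.94). Among those highest throughout were Zbtb16 (2.92, 4.55, 3.47), Klf15 (2.41, 4.65, 2.97), Xdh (2.02, 2.74, 3.40), the clock output gene Dbp (3.23, 3.13, 1.89) and Klf9 (1.72, 2.56, 2.32). Of 57 cell cycle genes tested in all 3 organs 43 were lower in each, in both fits, as were 26 of 40 matrix genes (22 as labelled), 14 of 21 fetal growth regulators (11 as labelled) and 12 of 21 imprinted genes (9 as labelled). The liver genes Alb, Apoa1 and Ttr, 3 of 5 tested, were also lower in each (2 of 6 as labelled). Without the 2 arrays Alb was uneven at 1 week, at 451 to 11530 in kidney, 182 to 1054 in heart and 257 to 1333 in lung. Of 19 clock genes 10 were higher in all 3 (9 as labelled), as were 9 of 17 glucocorticoid response genes (8 of 18 as labelled) and 12 of 27 xenobiotic genes (3 of 28 as labelled). Across genes, which are not independent replicates, the 8 against 1 week changes of kidney and lung had a Pearson correlation of 0.45 and a Spearman correlation of 0.36, and as labelled 0.37 and 0.24.

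**Figure D3:**
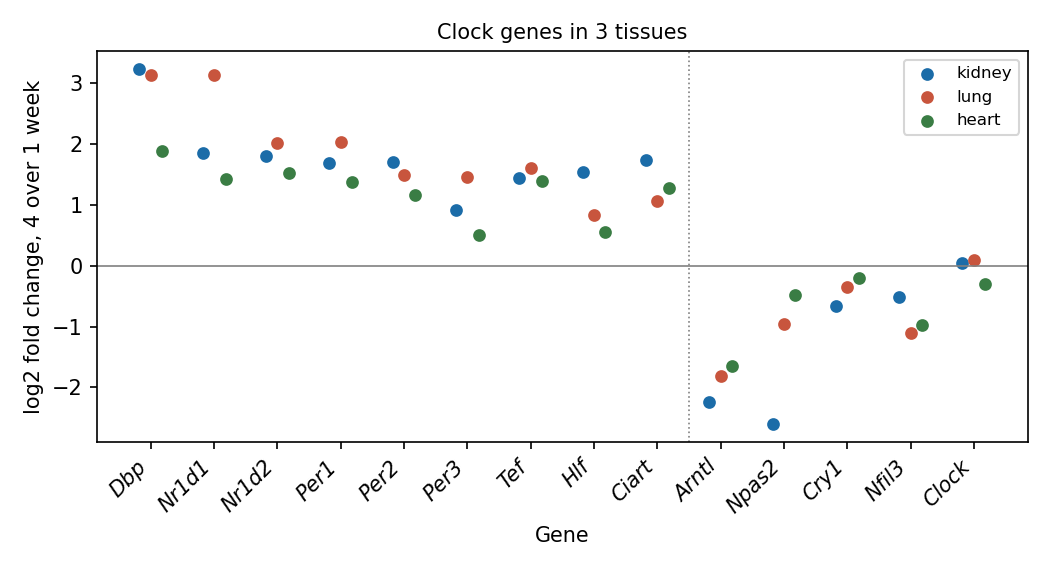
Log2 fold change from 1 to 4 weeks of 14 clock genes in kidney, lung and heart, 1 point per gene and tissue, from the fit without the 2 arrays whose transcripts contradict their label. The 9 output and feedback genes left of the dotted line lie above 0 in all 3 tissues, and Arntl, Npas2, Cry1 and Nfil3 lie below 0.

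Differences between organs in the change with age were tested themselves, with all arrays in 1 fit. Between 1 and 8 weeks the changes of Serpina1f, Hpd and Rdh16f2 were more positive in kidney than in lung (differences of 6.92, 5.78 and 5.09 on the log2 scale), Serpina6 (-6.69), Defb19 (-4.73) and Hdc (-6.17; as labelled -7.13) had the more negative change in kidney, and Slc4a1 (5.17) the more negative one in lung. Hspa1b differed by -4.48 and the fat cell gene Adipoq by -4.55 (SE 1.38), both more positive in lung. The signal of Adipoq was uneven within groups, at 7338 on lung 8 weeks replicate 3 and 289 to 1935 on the other lungs of that age. It was 112 to 1136 in kidney at 1 week and 3.4 to 431 at 8 weeks. Between 1 and 4 weeks Ghr rose in kidney (1.45) and fell in lung (-0.57), and as labelled the difference was 1.86; Agt fell in lung and differed by 5.68 (as labelled 4.69). Against heart, kidney differed among others in Tnni1 (8.64; as labelled 7.35), Kcnd2 (-5.08) and Cd163 (-4.33), and lung in Tnni1 (7.87; as labelled 4.85), Hspa1b (4.13) and Rpl3l (-3.60; as labelled -5.13).

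Without the 2 arrays 4545 genes differed between kidney and lung from 1 to 8 weeks (4063 as labelled) and 3931 from 1 to 4 weeks (3429 as labelled). From 1 to 4 weeks 3511 differed between kidney and heart (2419 as labelled) and 2655 between lung and heart (3477 as labelled). In simulated data 22.7% of the calls between kidney and heart and 12.5% of those between lung and heart were false, against 8.8% and 8.0% with a spread for each tissue, a fit added after that was seen; with it the counts without the 2 arrays were 2735 and 2488. Changes called in 1 organ and not in another were otherwise not tested for a difference.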

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

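The tests of an exchange, of mixing, of muscle, of the time of day and of glucocorticoid were chosen only after the results were seen, as were the fits without the 2 arrays; the splits of arrays and the scaling test were set beforehand.

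The array labelled heart 1 week replicate 5 carried lung transcripts and the array labelled lung 1 week replicate 4 carried heart transcripts. The mean of the cardiomyocyte list lay far from the other arrays of the group on both (10.26 against 13.96 to 14.21, and 13.73 against 8.69 to 10.04), as did the muscle list on the array labelled heart (8.43 against 6.50 to 6.94) and the Schwann cell list on the array labelled lung (7.81 against 8.48 to 8.71). Partial mixing is argued against, since the markers of the labelled organ were at 4.2% of their level on the array labelled heart and 4.9% on the array labelled lung, where other arrays of the organ not labelled had 2.6% and 4.7%, while markers of the other organ reached 98.0% and 90.4%. An exchange of both arrays may be the explanation: the array labelled heart correlated at 0.980 with lung 1 week, where the lowest of those arrays had 0.979 (a margin of 0.001), and the array labelled lung at 0.973 with heart 1 week against 0.961, while the correlations with 4 weeks were 0.949 and 0.951. The labels alone decide the groups, so the arrays were not moved, and no biological explanation was tested.

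Skeletal muscle transcripts were high on some lung arrays. The list mean was 8.18 and 7.93 on lung 1 week replicates 3 and 5, and 8.59, 9.64 and 7.37 on lung 8 weeks replicates 1, 3 and 5, with 6.05 to 7.03 on the others. Muscle taken along with some lungs is a candidate explanation: the 19 members moved together over the lung arrays, with a median correlation of 0.60 where random lists of that size reached 0.29 at most. A change with age stays open too. Without the 4 richest arrays the list's median change from 4 to 8 weeks was 1.15 (adjusted p = 1.3e-06 in camera with the preset correlation). With them it was 2.03 (adjusted p = 8.1e-08, and 0.375 with an estimated correlation). The fit without the 4 still held lung 8 weeks replicates 4 and 5, at 7.03 and 7.37. The lungs of 4 weeks had 6.05 to 6.37, so that fit cannot tell a change with age from muscle taken along. Neither explanation is excluded.

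The 9 clock output genes were higher at 4 weeks than at 1 week in all 3 organs. Of 17 glucocorticoid response genes 9 were (8 of 18 as labelled). Scaling is argued against as the cause, since the median of the 9 output genes (1.70 in kidney, 1.61 in lung, 1.37 in heart) fell by at most 7.1% under another scaling. Another time of day at collection may contribute: the 5 genes of the opposite phase had medians of -0.67 in kidney, -0.96 in lung and -0.48 in heart. Their errors here (0.65, 0.41 and 0.34) come from the spread across those 5 genes and hold no error between arrays. The members were uneven, in kidney from -2.61 for Npas2 to 0.05 for Clock. Higher glucocorticoid signalling may contribute as well, but its test cannot decide this, since the genes tested are part of the pattern to be explained. The glucocorticoid list without its clock genes had medians of 1.13, 1.33 and 0.89. In camera its p was 0.00689, 2.9e-09 and 4.9e-07 with the preset correlation, and 0.105, 0.00623 and 0.0469 with the estimated one. The collection times are not in the labels, maturation of either system with age was not tested apart from these, and all of these stay open.

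In the control probes, some arrays lay far from the others of their group. The poly-A labelling controls were at 11.79 on kidney 4 weeks replicate 3 (others 10.58 to 10.91), 12.58 on heart 4 weeks replicate 1 (11.29 to 11.57) and 11.18 on lung 4 weeks replicate 1 (10.02 to 10.04). The hybridization controls were at 12.80 on heart 1 week replicate 1 (others up to 12.22), 12.54 on kidney 4 weeks replicate 3 (11.68 to 11.90) and 12.94 on kidney 8 weeks replicate 5 (11.74 to 12.02). The actin 3' minus 5' difference was 0.99 on kidney 8 weeks replicate 5 (0.73 to 0.79). It was 1.43, the highest of all 40 arrays, on kidney 4 weeks replicate 1 (0.61 to 0.96) and 0.34 to 0.51 on the kidneys of 1 week. It therefore moved with age in kidney. The Schwann cell list was at 7.21 on kidney 1 week replicate 1 (7.79 to 7.89). Chance gives about 1 such array in 20 groups tested, and 96 groups were tested.

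Changes differed between organs for 4063 genes (kidney and lung, 8 against 1 week), 3429 (kidney and lung, 4 against 1 week), 2419 (kidney and heart) and 3477 (lung and heart) as labelled, by the test of the difference. The difference for Ghr between kidney and lung from 1 to 4 weeks was 1.86 (1.45 against -0.41).

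Each count of changed genes was set against 100 splits of the arrays between ages, the real one included. For the within-organ counts no other split reached the real one (1 of 100 each, the lowest share possible), so a chance division of the arrays is argued against. These splits cannot tell age from anything else that differed between the age groups. The kidney counts were 5827, 85 and 6472 (4 against 1, 8 against 4 and 8 against 1 week) with the highest other at 171, 2 and 1. In lung 3982, 15 and 4629 stood against 823, 2 and 552, and in heart 2451 against 1. Without the 2 arrays the lung counts of 5484, 281 and 6075 stood against 3696, 2 and 3870 and the heart count of 3404 against 998. For the correlation of 0.37, as labelled, the highest other was 0.33. Leaving out lung 1 week replicate 5 alone also gave 0.33. Ages were exchanged within each organ, so these splits cannot decide whether the changes of both organs are related. For genes lower and higher in all 3 organs (559 and 153) the highest other was 0 in limma and for the continuation in kidney and lung (66 and 9) it was 1 and 1. The within-organ splits changed too few genes in heart (at most 1) or between 4 and 8 weeks (at most 2) for any larger number, so nothing about sharing or continuation follows from them. With the 4-week arrays split between the steps, lung as labelled had medians of 1 same and 2 opposite. For the differences between organs the real values of 4063, 3429 and 3477 exceeded the highest other splits (1791, 969 and 3206). For kidney and heart (2419) 1 other split gave more, 3681, which makes 2 of 100. These splits exchanged ages within each organ, with all arrays as labelled. They ask whether either organ changed with age, so they cannot decide whether the changes differed between organs.

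The splits cannot decide whether chance gave the numbers of lists called. A split that leaves the ages unequally mixed keeps part of the change with age, so it is no baseline without change. As many were called in 10, 28 and 5 of 100 splits for kidney (20, 7 and 20 real, highest other 23, 14 and 23), in 14, 8 and 17 for lung (23, 11 and 23 real, highest other 27, 14 and 26) and in 25 for heart (18 real, highest other 24).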

How the results depend on the processing

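The fits without the 2 arrays that contradict their label, the poly-A block, the sets without muscle-rich or poly-A-high arrays, the offsets of 1 and 64 and the spread for each tissue were chosen only after the data were seen. The values below come from all arrays as labelled unless they are said to be without the 2 arrays (the sets without muscle-rich arrays always leave these out too), so they stand against 15 genes for lung 8 against 4 weeks and 2451 for heart. In those fits, except where given here, the counts stayed within 1.5 times and the named genes and lists kept their direction. The fit without the 2 arrays was run only with the estimated correlation, fry, the poly-A block, the muscle-poor sets, the spread for each tissue and, for counts, leaving out 1 array, so for lung and heart values from that fit the other alternatives are untested. For the rest all alternatives named above were run, and the cause of a change was not tested unless given. Quantile normalization and median centring moved the median change of all tested genes by at most 0.09. Signal over background limits dim genes, whose fold depends on the offset.

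With treat over 1.5-fold, which asks for a larger change, the counts were 1471, 3 and 1759 in kidney (4 against 1, 8 against 4 and 8 against 1 week), 535, 0 and 715 in lung (limma without treat gave 1072 genes with an unadjusted p under 0.05 for the count of 0) and 265 in heart. Requiring 2-fold left 144 genes lower and 30 higher in all 3 organs and a continuation of 22 in kidney and 1 in lung. With array weights kidney 8 against 4 weeks had 253 genes, lung 324, heart 4553, kidney and heart differed in 3687, 954 were lower and 377 higher in all 3, the correlation was 0.45 and the continuation 169 in kidney and 130 in lung. Median centring gave 49 genes for kidney 8 against 4 weeks and a continuation of 39 in kidney and 5 in lung. The 60th percentile gave 24 genes for lung 8 against 4 weeks, a continuation of 17 and a correlation of 0.41, and no filter a correlation of 0.28. All arrays in 1 fit gave 29 genes for lung 8 against 4 weeks and 4510 for heart, and an intensity trend 24 for lung 8 against 4 weeks. An offset of 64 gave a continuation of 14 in lung. With the replicate number as a block, which does not pair the arrays, lung 8 against 4 weeks had 6 genes and a continuation of 2.

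Without the 2 arrays lung 8 against 4 weeks had 281 genes, 323 genes were higher in all 3, the correlation was 0.45 and the lung continuation 131. With the poly-A block as well the numbers were 281, 383, 0.46 and 131, with 4291 for heart, 3967 for kidney and heart and 923 lower in all 3. The poly-A block gave 139 genes for kidney 8 against 4 weeks and a continuation of 101, with and without the 2 arrays. Leaving out 5 lung arrays rich in muscle gave 9 genes for lung 8 against 4 weeks, and the set of 4 gave 56; fewer arrays were tested. With an estimated correlation 11, 2 and 10 lists were called in kidney, 6, 1 and 6 in lung and 0 in heart (camera with the preset correlation called 18 in heart), and fry called 3 for 8 against 4 weeks in kidney and 3 in lung. The estimated correlation took the call from 86 list results and fry from 29.

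Among the other named genes and lists, calls were lost and gained, with the direction kept, as follows: 11 and 0 with no filter, 6 and 1 with the 60th percentile, 10 and 2 with the mean of probe sets, 11 and 3 with quantile normalization, 7 and 2 with median centring, 13 and 11 with array weights, 5 and 2 with all arrays in 1 fit, 42 and 0 with treat, 11 and 1 with the replicate block, and 8 and 7 without the 2 arrays. They were 1 and 0 with an offset of 1 or 64, 5 and 0 with the poly-A block, 11 and 1 without the 4 poly-A-high arrays, 18 and 3 without 5 muscle-rich arrays, 5 and 4 without 4, 6 and 0 without both marked heart arrays, 2 and 0 with a spread for each tissue, and 0 and 0 with the intensity trend and the animal block (same side of the threshold in limma for 250 and 40 results).

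Leaving out 1 array at a time gave, as lowest and highest, 5417 to 6133, 50 to 110 and 5931 to 6800 genes in kidney, 3356 to 5484, 8 to 281 and 3984 to 6075 in lung and 1609 to 3404 in heart. The differences ranged from 3554 to 4669 and 2888 to 4065 (kidney and lung, 8 and 4 against 1 week), 2180 to 2875 (kidney and heart) and 2640 to 4032 (lung and heart), the shared genes from 454 to 720 (lower) and 117 to 226 (higher), the correlation from 0.33 to 0.45, and the continuation from 43 to 83 in kidney and 4 to 131 in lung. Lists called ranged over 19 to 21, 5 to 9 and 19 to 20 in kidney, 19 to 26, 8 to 14 and 19 to 24 in lung, and 17 to 24 in heart. Without the 2 arrays the lung and heart counts ranged from 4901 to 5531, 115 to 278, 5503 to 6126 and 2666 to 3687.

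Direction reversed for single genes, the cause not tested; ranges leaving out 1 array run from the lowest to the highest value. Fignl1 in kidney 8 against 4 weeks was at 0.27 with quantile normalization and 0.36 with an offset of 1. In both settings the probe set of each gene was chosen anew, and whether that of Fignl1 changed was not checked. Igf2bp3 in heart was at -1.53 with the mean of its probe sets, and in lung 8 against 4 weeks at 0.01 with quantile normalization, 0.03 with median centring, 0.03 without 5 muscle-rich arrays and -0.13 to 0.02 leaving out 1 array. Cdkn1c in lung 4 against 1 week was at -0.22 with array weights, -0.23 without the 2 arrays (also with the poly-A block), -0.21 in both muscle-poor sets and -0.23 to 0.11 leaving out 1 array. In kidney 8 against 4 weeks, leaving out 1 array put Igf2 at -0.16 to 0.08, Mycn at -0.25 to 0.03, Mest at -0.01 to 0.14, Sftpc at -0.18 to 0.11 and Xist at -0.24 to 0.14. Mest was also at -0.01 without the 4 poly-A-high arrays, Dlk1 at -0.01 with the poly-A block (both fits) and Xist at 0.00 with an offset of 1.

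Sftpc in kidney 8 against 1 week was at -0.12 with array weights, -0.15 to 0.17 leaving out 1 array, -0.10 with the poly-A block (both fits) and -0.15 without the 4 poly-A-high arrays, and in kidney 4 against 1 week at -0.02 with weights, -0.09 to 0.21 leaving out 1 array and -0.01 without those 4. Xist in kidney 8 against 1 week was at -0.04 to 0.33 leaving out 1 array, -0.05 with the poly-A block (both fits) and -0.04 without those 4, and in 4 against 1 week at -0.04 to 0.42 leaving out 1 array. Leaving out 1 array put Six2 at -0.03 to 0.33 in kidney 4 against 1 week, -0.02 to 0.28 in heart, -0.29 to 0.30 in lung 8 against 4 weeks and -0.37 to 0.24 in lung 4 against 1 week. In lung 8 against 1 week Six2 was at 0.03 with array weights, -0.23 to 0.06 leaving out 1 array, 0.05 without the 2 arrays (also with the poly-A block), 0.71 without 5 muscle-rich arrays and 0.48 without 4, and in 4 against 1 week at 0.33 in both muscle-poor sets. Sftpc in lung 8 against 4 weeks was at -0.37 with the mean of its probe sets, -0.04 with weights and -0.11 to 0.09 leaving out 1 array, and in heart at 0.08 with weights. Myh6 in lung 4 against 1 week was at 0.01 without the 2 arrays (also with the poly-A block), -1.45 to 0.01 leaving out 1 array and 0.43 in both muscle-poor sets, and in 8 against 1 week at 0.25 without 4 muscle-rich arrays. Myh7 in lung 8 against 1 week was at 0.46 without 5 muscle-rich arrays and 0.35 without 4.

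The list values given next are not log2 changes. They are negative decimal logarithms of the unadjusted camera p, with the sign of the list's direction. The lung list of fetal cardiac sarcomere genes turned to 0.05 without 5 muscle-rich arrays and 0.09 without 4 (4 against 1 week). It turned to 0.04 without 4 (8 against 1 week). The list of adult cardiac contraction turned to 0.30, 0.26 and 0.12 in the same settings. Values this small give no evidence of a direction.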

Other observations

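The difference in cell cycle change between kidney and lung was tested after the lists had been seen to disagree between both correlations in camera, and both permutation tests of it were chosen then; the prediction for camera was set before.

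In kidney 8 against 1 week the lists of macrophages (6 rose, 4 fell, 8 did not pass, adjusted p = 0.721), T and NK cells (2 rose, 1 fell, 5 did not pass, 0.639), B and plasma cells (1 rose, 7 did not pass, 0.227), erythroid cells (4 rose, 1 fell, 5 did not pass, 0.265) and neutrophils and mast cells (5 fell, 8 did not pass, 0.258; S100a9 at -2.31) were not called. Nor were the lists of adipocytes (2 rose, 3 fell, 0.805; Ucp1 at -3.94), thymocytes (3 fell, 0.518), liver (3 rose, 5 fell, 0.639; Apob at 3.85 and Ahsg at -3.39), adrenal gland (2 rose, 0.721) and Schwann cells (3 fell, 0.227). The growth lists of cell cycle inhibitors (3 rose, 5 fell, 0.335), ribosomal proteins (3 fell, 0.265), nephron progenitors (2 rose, 5 fell, 0.487; Wnt4 at -2.29) and immediate early genes (3 rose, 7 fell, 0.265) were not called either. The lists of alveolar type 2 cells (4 rose, 4 fell, 0.529), alveolar type 1 cells (1 rose, 6 fell, 0.119), airway cells (3 rose, 2 fell, 0.219) and adult cardiac contraction (3 rose, 5 fell, 0.881) were also not called. The median and the mean differ in sign there for macrophages, adult cardiac contraction and adipocytes, and the test and the mean for macrophages, adipocytes and adrenal gland. The skeletal muscle and cardiomyocyte lists had under 5 tested members in kidney.

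In lung without the 2 arrays, the skeletal muscle list (2 rose, 1 fell, adjusted p = 0.275), adipocytes (8 rose, 1 fell, 0.118; as labelled 4 rose), endothelium (8 rose, 3 fell, 0.238; as labelled 0.0357) and cardiomyocytes (none passed in limma, 0.843) were not called from 1 to 8 weeks. In heart the imprinted (12 fell, 1 rose, adjusted p = 2.2e-05; adjusted p = 0.147 with an estimated correlation), glucocorticoid (11 rose, 4.4e-07; 0.147) and clock (10 rose, 2 fell, 0.00167; 0.0721) lists were called, with Plagl1 at -2.25, Klf15 at 2.97 and Arntl at -1.65.

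Cell cycle genes fell further in kidney than in lung between 4 and 8 weeks, by a median difference of -0.52 (adjusted p = 2.3e-17 with the preset correlation and 0.181 with the estimated one). The list mean fell by 0.65 in kidney (exact p = 0.00794) and by 0.11 in lung (exact p = 0.167), and the difference was -0.54. The first permutation test exchanged ages within each organ, which asks whether either organ changed and not whether they differed, and gave p = 0.0213. It was therefore followed by one that exchanged organ labels within an age after centring each organ, with 63504 assignments, which is approximate and gave a permutation p = 1.6e-04.

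For the expression of Six2, a nephron progenitor gene, no change passed in kidney from 1 to 8 weeks (0.46, adjusted p = 0.137).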
